A study of Mytilus galloprovincialis with 8 samples.

How the data were processed

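RNA from gill was labelled with Cy3 and hybridised to 1-colour Agilent arrays, 8 in all on 3 slides, each holding a pool of 5 mussels, per the labels and the series' design text. Images were read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The deposited intensity of each spot is the processed signal after detrending within the array, with substitute values near background, per the file headers. No step between arrays is recorded in those files. The authors' deposited value table is on a log2 scale with the same distribution in every column and a median of 7.18 in each. Equal distributions are what quantile normalization gives, so the table is read as quantile normalized and is not independent of the quantile alternative; no source used here states the method. Each column correlated best with its own array, so the direction of its values is that of the scanner signal.

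Each array had 61392 spots, of which 1853 were control spots and were left out. Spots marked as outliers (6 to 46 per array) were left out and spots of one probe were averaged; 25 probes were spotted 10 times. Signals were taken as log2 and each array's 75th percentile over non-control spots was subtracted. Probes well above background on at least 4 of the 8 arrays were tested: 38926 of 59314 (65.6%), for 20505 transcripts. Only 2 spots over all arrays were saturated.

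Fast and slow pools were compared per probe with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists were tested on transcript means with camera (preset correlation 0.01, and estimated) and fry. Single values were compared by exact permutation over all assignments of 4 and 4, and also with same-numbered pools kept as pairs. The script was tested on simulated data for the fast against slow comparison, with 38926 probes drawn from the real means and SDs and 200 changed. At log2 changes of 1, 1.5, 2 and 3 it recovered 46%, 70%, 68% and 86% of the 50 probes changed at each size, with 5 false calls. The simulated noise was independent between probes and arrays, without slides or pairs. These shares therefore check the script and need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

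Main tests, alternatives and 30 gene lists were fixed before the data were examined. Every probe description in the files was uninformative, and 0 of the 25753 identifiers matched the gene table of assembly xbMytGall1.hap1.1. Only 2 fixed lists matched an identifier. The patterns looked for spelled-out names, so the lists for the respiratory chain, tubulins and ribosomal proteins missed the short or joined names on the array. One was elastase, which was not tested because it was dim. The other was the RNA-binding transcript, caught by the gonad list only because its pattern is part of the word binding, so it is a false match. The lists of 12 female-lineage and 11 tested male-lineage mitochondrial transcripts and of 7 tested named nuclear genes were formed from the probe names after the files were seen and before any fit. The files do not define F and M.

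Named genes followed a rule: among annotated transcripts, one probe per name, the 12 with the largest passing change each way, filled up by smallest unadjusted p. None passed, and the rule gave 12 names higher in fast pools, the most it allows, and 3 lower. On transcript means, 12 of 12 female-lineage, 10 of 11 male-lineage and 5 of 7 nuclear names were higher. The 4 serial-number identifiers in the text fall outside that rule.

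The labels number the pools 1 to 4 in each group. Deviations from the group means of same-numbered pools correlated at 0.122, 0.137, 0.131 and 0.227, each over the limit set beforehand. Same-numbered pools were therefore also treated as pairs. The highest correlations of slow pools 1 to 4 with a differently numbered fast pool were 0.085, 0.102, 0.128 and -0.00090, so for pool 3 the margin was small. What the numbers mark is not given in the labels used here. Pools 1 and 2 shared slide 1, pool 3 was on slide 2 and pool 4 on slide 3, with both groups on each slide; whether slide accounts for the pairing was not tested.

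The alternatives were normexp background correction (offset 50), quantile and median scaling, 2 other filters on dim probes, keeping outlier spots, the authors' table, slide and pool number as blocks, a variance trend, array weights, an unmoderated test, transcript means, and leaving out each pool. Blocks of slide 1 against slides 2 and 3, alone and with a filter, scaling to 7 spike-in probes, limiting the spread of the male-lineage list to probes well above background on all arrays, and exact tests that keep same-numbered pairs were chosen after seeing the data.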

Results

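Gene expression was measured in the gill of the Mediterranean mussel *Mytilus galloprovincialis*, the organ that drives the feeding current and takes up oxygen. The animals had been reared for 7 months in the laboratory with daily exposure to air, and were then sorted into fast and slow growers. Each of the 8 arrays held RNA pooled from 5 mussels, with 4 fast pools and 4 slow pools, so 20 mussels stood behind each group. The arrays carried 59314 probes for 25753 transcript identifiers. Of these identifiers, 34 were gene names and the others were serial numbers of sequence assemblies, which no table used here tied to a gene. The share of probes well above background ran from 56.7% in fast pool 1 to 70.5% in fast pool 4, and averaged 64.9% ± 6.15 (SD, n = 4) in slow and 63.4% ± 6.35 (SD, n = 4) in fast pools. The 75th percentile of the raw signal was 8.82 ± 0.08 log2 units in slow and 8.57 ± 0.19 in fast pools (SD, n = 4 each; exact two-sided permutation p = 0.0286 over all assignments and 0.125 with same-numbered pools kept as pairs, each the smallest possible). The number of arrays limits the precision of every value below.

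The first comparison asked which gill transcripts differed between fast and slow growers. Under the main settings the transcript with the smallest p was mgal_est_14006, whose brighter probe stood at 5.80 ± 0.13 in slow and 7.29 ± 0.18 in fast pools (log2 relative to the array's 75th percentile, SD, n = 4), a 2.81-fold difference that did not pass (limma adjusted p = 0.173). It was higher in fast pools on each slide, by 1.46, 1.79 and 1.24 log2 units on slides 1, 2 and 3. The groups did not overlap for this probe, chosen by smallest p, so the shared direction was certain and is no further evidence. Its dimmer second probe, well above background on 2 slow and 4 fast arrays, differed by 2.11 log2 units in the same direction. With normexp background correction the brighter probe passed at limma adjusted p = 0.0289, and with a mean-variance trend at 0.0160. With median scaling it did not pass (limma adjusted p = 0.242), and a probe of mgal_nuc_1540 had the smallest value there, 0.216. All 3 probes of mgal_nuc_1540 were higher in fast pools, by 1.77, 1.19 and 1.88 log2 units, with a limma adjusted p of 0.239 for the first. These are differences of dim probes: the first was well above background on 1 slow and 4 fast arrays, and its difference was 0.67 with normexp background correction and 0.56 in the authors' processed values. In the other direction, 1 probe of mgal_nuc_26060 was lower in fast pools by a log2 difference of -2.01 and 1 probe of mgal_nuc_14117 also by -2.01, each with a limma adjusted p of 0.277. The probe of mgal_nuc_26060 was well above background on 4 slow arrays and 1 fast array, and its difference was -0.40 with normexp background correction and -0.58 in the authors' processed values. The second probes of these transcripts differed by -0.15 and 0.01, so the paired probes disagreed. These 4 identifiers were chosen by smallest unadjusted p after the values were seen, outside the rule for named genes.

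Over the 38926 probes tested, limma called 0 at an adjusted p under 0.05, and the smallest adjusted p was 0.173. That call rested on single pools: without slow pool 1 it called 5 probes (smallest limma adjusted p 0.00190) and without slow pool 4 it called 1 (0.0268), none of them a probe of the 4 identifiers above. The 5 were higher in fast pools by 4.35 to 7.42 log2 units with all pools and 6.08 to 10.32 without slow pool 1, and each was well above background on 5 of the 8 arrays. The other was lower, by a log2 difference of -4.41 with all pools. At an unadjusted p under 0.05 there were 3211 probes, or 8.25%, where 1946.3 would be expected with no difference. Of them 1527 were higher and 1684 lower in fast pools, so 47.6% were higher; with normexp background correction that share was 63.6%. The unmoderated equal-variance test also called 0, with 3379 at an unadjusted p under 0.05. Groups did not overlap for 2126 probes, or 5.47%, where chance gives 2.86%. A difference of at least 2-fold was seen for 1723 probes, 802 higher and 921 lower, and 440 of these had an unadjusted p under 0.01. Of the 1723 probes, 670 were well above background on all 8 arrays, 328 higher and 342 lower; the size of the others rests in part on values near background.

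**Figure D1:**
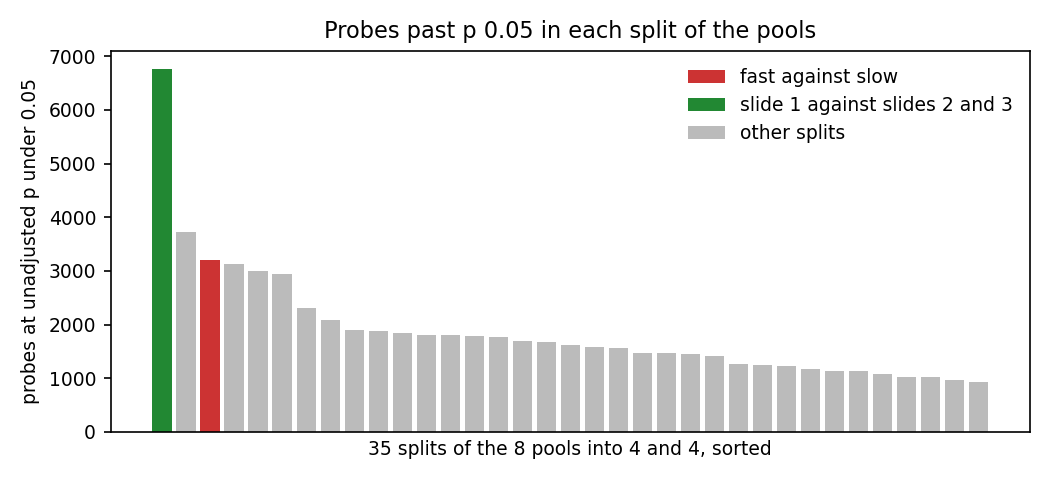
Number of probes at an unadjusted limma p under 0.05 (vertical axis) for each of the 35 ways to split the 8 pools into 4 and 4 (bars, sorted). The split by growth gave 3211 probes and the split by slide 6764.

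Under the main scaling, the named transcripts of the female-lineage mitochondrial genome were all higher in fast pools. Names ending in F or M on the array are read here, from background knowledge and not from the files, as the female- and male-inherited mitochondrial genomes that *Mytilus* carries. The 12 female-lineage transcripts encode subunits of the respiratory chain and of ATP synthase. Their mean level was 7.65 ± 0.06 in slow and 7.87 ± 0.09 in fast pools (log2, SD, n = 4), a difference of 0.22 or 1.17-fold (exact two-sided permutation p = 0.0286 over all assignments and 0.125 with same-numbered pools kept as pairs, each the smallest possible). All 12 transcripts and all 36 probes had the same direction under the main scaling. The 75th percentile subtracted in that scaling itself differed by -0.25 log2 units between fast and slow pools, about the size of this difference. The higher level is thus relative to other probes of the array and does not show a higher raw signal. The largest differences were 0.43 for ND4L, 0.32 for ND3, 0.30 for ND4 and 0.30 for ATP6, and the smallest was 0.06 for ND5. ND3, ND4, ND4L and ND5 are subunits of NADH dehydrogenase, and ATP6 is a subunit of ATP synthase. COX1, COX2 and COX3, subunits of cytochrome c oxidase, differed by 0.17, 0.21 and 0.21, and cytochrome b by 0.20. None passed alone: 0 of the 12 had an adjusted p under 0.05 in limma adjusted over the list alone (smallest 0.0928) or over all transcripts, and 9 of the 36 probes had an unadjusted p under 0.05.

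As a list, the female-lineage transcripts passed camera at an adjusted p of 1.17e-05 with a preset correlation, and fry at an adjusted p of 0.0167. The correlation estimated for this list was 0.303, well above the preset 0.01, and with it the call was lost (camera adjusted p = 0.174). The difference was 0.25, 0.22 and 0.18 on slides 1, 2 and 3. It was 0.04 after quantile normalization (camera adjusted p = 0.396), where 7 of the 12 were higher, and 0.04 in the authors' processed values (camera adjusted p = 0.299), which look quantile normalized too, so these are not independent. Other bright transcripts moved the same way: of the 50 brightest outside the mitochondrial lists, 45 were higher in fast pools, with a median difference of 0.15. Measured in each pool against the 20 transcripts closest in brightness to each member, the list differed by 0.10 (exact two-sided permutation p = 0.2).

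**Figure D2:**
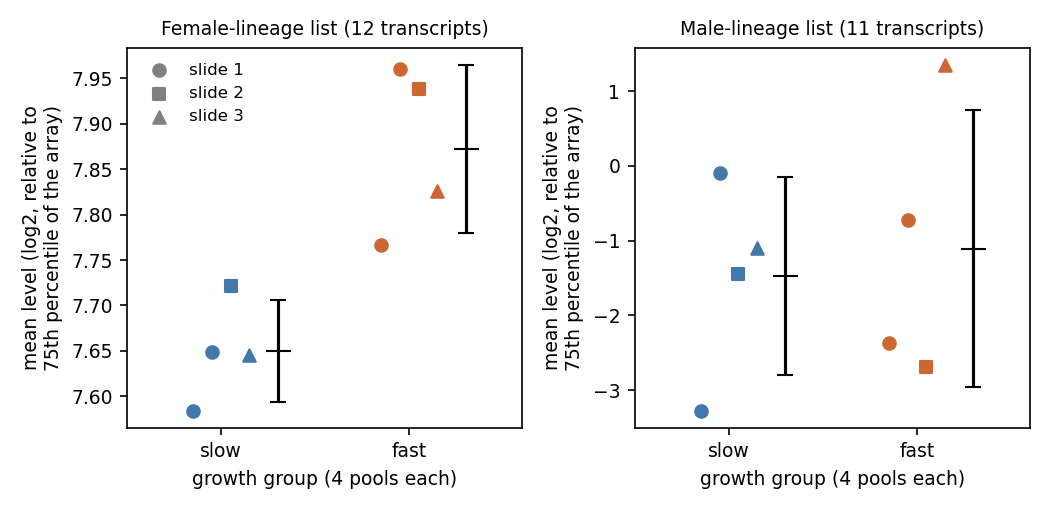
Mean level of the female-lineage (left) and male-lineage (right) mitochondrial lists in each pool, in log2 units relative to the array's 75th percentile; points are pools, shapes are slides, and bars are the group mean ± SD (n = 4). The 4 fast pools lie above the 4 slow pools on the left under this scaling, while on the right, where the mean includes probes near background in some pools, they range from -3.27 to 1.35.

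The male-lineage transcripts spread widely between the pools of each group. Over 11 tested transcripts the mean was -1.48 ± 1.33 in slow and -1.11 ± 1.85 in fast pools (log2, SD, n = 4; exact two-sided permutation p = 0.743). The difference of 0.37 turned to -0.23 without slow pool 1 and to -0.45 without fast pool 4, and rose to 0.83 without slow pool 2 and to 0.90 without fast pool 3. With the preset correlation, the list did not pass camera with all pools (adjusted p = 0.394). It passed at that correlation without slow pool 2 (camera adjusted p = 0.0423) or fast pool 3 (0.0366). The correlation estimated with all pools was much higher, at 0.733. With the estimated correlation and all pools, camera gave an adjusted p of 0.698, and fry gave 0.719. Of the 36 male-lineage probes, 11 were well above background in slow pool 1 and 31 in slow pool 2, while all 36 female-lineage probes were so in every pool. The slide differences were 0.14, -1.25 and 2.44. On the 9 probes, of 6 transcripts, that were well above background on all 8 arrays, the mean was 0.84 ± 0.91 in slow and 1.30 ± 1.39 in fast pools (log2, SD, n = 4; exact two-sided permutation p = 0.657).

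The 7 tested nuclear genes with names showed no difference that passed. Alpha tubulin, a component of microtubules, differed by -0.22 ± 0.12 (SE), a ribosomal transcript by 0.20, a 40S ribosomal transcript by 0.17 and ribosomal protein P0 by 0.11. Actin differed by 0.05, elongation factor 1 alpha by 0.04 and an RNA-binding transcript by -0.06. The mean of the list was 0.04 higher in fast pools (exact two-sided permutation p = 0.4), and its sign turned after quantile normalization (-0.09), without a filter on dim probes (-0.04) and in the authors' processed values (-0.12). Collagen and elastase were well above background on 2 slow arrays and 1 fast array each, and a contactin-associated transcript on none. Of the 30 gene lists fixed beforehand, 0 had the 5 tested members needed for a test. Their patterns looked for spelled-out names and missed the short mitochondrial names and the joined nuclear names on the array. Apart from the mitochondrial transcripts described above, no pathway could be described.

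The last comparison asked whether the whole profiles separated by growth. Correlations between arrays ran from 0.923 to 0.955, with a mean of 0.945 within and 0.940 between growth groups. The mean distance between groups exceeded that within groups by 0.0049 (exact one-sided permutation p = 0.0571 over all 70 assignments). The same test gave p = 0.0286 with normexp background correction and in the authors' processed values, while without a filter on dim probes the excess was 0.00106 (p = 0.286). Keeping same-numbered pools as pairs leaves 8 splits and a smallest p of 0.125, so under that pairing no setting could pass. For slides the same measure was 0.0047 (exact one-sided permutation p = 0.0905 over 420 assignments).

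**Figure D3:**
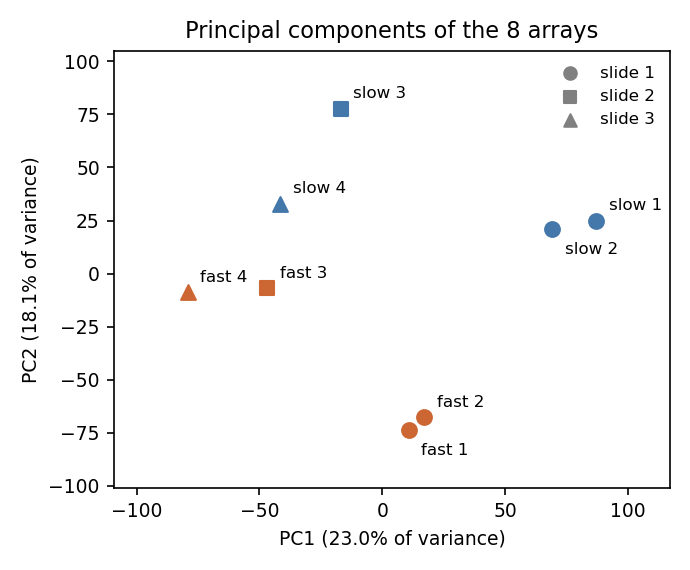
First and second principal components of the 8 arrays (23.0% and 18.1% of the variance), with growth group by colour (blue slow, orange fast) and slide by shape. Along the first component the pools of slide 1 lie to the right of those of slides 2 and 3, and along the second the slow pools (20.96 to 77.7) lie above the fast pools (-73.6 to -6.86).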

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

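The tests of slide batch in both mitochondrial lists, of cross-hybridisation, of the 2 probe counts over other splits, and of agreement between probes were chosen only after the result was seen. For the brightness test, the candidate sizes other than 200, the match on GC as well and the comparison per pool were also added after its first result was seen. The limit of the male-lineage list to probes well above background on all arrays was chosen after the spread of the whole list was seen.

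The first pattern was the higher level of female-lineage mitochondrial transcripts in fast pools, 0.22 log2 units. Each slide held equal numbers of fast and slow pools, so a shift shared by the arrays of a slide cancels out of this difference. That balance also fixes the value with slide as a block, 0.222. The smallest difference on a slide was 0.18. Every fast pool lay above every slow pool, so its sign was fixed and it is no further evidence. Among the 35 splits of the pools, 1 gave a camera p as small as the real 3.89e-06, the real one itself, and the smallest of the others was 3.56e-05. A camera p under 0.05 with the preset correlation was common, with 13 of the 34 other splits giving one, and the largest difference among the 34 was 0.20. Among the 8 splits that part all 4 pairs the real one ranked 1, with 0.00217 the smallest of the others, and 8 splits are too few for a share under 0.05. Brightness cannot be told apart from a mitochondrial difference: random lists matched on brightness differed by 0.13 on average, the list lay outside their central 95% at 5 of 6 candidate sizes and inside at the size of 500. At that size the match was loose, with candidates at a mean level of 5.49 against 7.76 for the list. Lists matched on brightness and GC content averaged 0.0998, with a range of -0.066 to 0.264 that holds the list. Their candidates stood at 4.28, so this match was loose as well. These intervals leave out the spread between pools (SE 0.053 with slide as a block, same-numbered pairs not kept). Against matched transcripts in the same pools, exact permutation p over all assignments ran from 0.143 to 0.343, and pairs were not kept there either. GC content stays open as well, since GC-matched lists averaged 0.0226 with a range of -0.23 to 0.26 that holds the list, as does growth itself, which the design names.

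The second pattern was the spread of male-lineage transcripts over pools, 3.84 log2 units or 14.3-fold on the 9 probes well above background on all 8 arrays, and 2.05 log2 units or 4.14-fold without fast pool 4, the highest. As the source of this spread, cross-hybridisation from female-lineage transcripts is argued against, since that range was 10.2 times theirs, and 5.46 times without fast pool 4. A steady contribution of female-lineage signal to these probes was not tested. Slide batch cannot be told apart: the pools of slide 1 covered 0.407 of the range on these probes, but 0.763 without fast pool 4 and 0.688 on the whole list, which holds probes near background. The 2 pools of slide 3 differed by 2.13 log2 units, or 0.554 of the range, which a slide alone would not give, but that too rests on fast pool 4. Other material in unequal amounts cannot be told apart: 15 nuclear transcripts followed the level of the whole list with r above 0.9, where 100 reorderings of the pools gave a median of 17.5 and 60 of them gave as many. The level of the 9 probes was followed by 23, a count not set against reorderings. The sex of the pooled mussels, not given in the labels used here, was not tested.

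The third pattern was the difference between slide 1 and slides 2 and 3, with 1391 probes at a limma adjusted p under 0.05, 1293 of them lower on slide 1. Slide 1 also had fewer probes well above background (58.8% against 69.4%) and higher negative controls (2.75 against 1.78 log2 units). As the whole cause, dim probes are argued against by a ratio of 0.644 between the shares called above and below the median brightness. They were still called more often, at 4.35% against 2.80% of the brighter probes, so a part for them stays open. The filter also admits probes well above background only on the 4 arrays of slides 2 and 3, which this ratio does not set apart. GC content as the whole cause is argued against by 1200 calls after centring within 20 GC bins. Intensity-dependent scaling as the whole cause is argued against by 1094 calls after quantile normalization. Pools on the slides were different mussels, so slide and pool stay open; no biological explanation was tested.

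Of 3211 probes at an unadjusted p under 0.05 between fast and slow pools, 3 of the 35 splits gave as many, with 6764 the highest of the others, so a chance division of the pools cannot be excluded. That highest split follows the slides and points to a structure of the samples; with slide as a fixed block the growth comparison gave 4043 probes and 0 calls. All 35 splits gave at least the 0 probes called at an adjusted p under 0.05, the highest other being 1391. With a real count of 0 no split could give fewer, so this comparison decides nothing. With same-numbered pools treated as pairs, the real split ranked 1 among the 8 that part all 4 pairs, the next having 1559 probes at an unadjusted p under 0.05.

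Slow pool 1 stood apart from the other slow pools for a probe of ND1_mgal_F (7.88 against 8.06 to 8.07). Slow pool 4 did so for a probe of COX1_mgal_F (8.97 against 9.25 to 9.30), and fast pool 4 for ND4_mgal_M (-0.95 against -5.60 to -5.21). These were 3 of 108 groups tested, where chance flags about 1 in 20. A control probe for an external RNA, ERCC-00062_278, gave signal in data outside the comparisons, 6.21 log2 units above the negative controls on average and well above background on all 8 arrays.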

How the results depend on the processing

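The count of 0 probes at a limma adjusted p under 0.05 became 1 with normexp background correction and 1 with a mean-variance trend, both times mgal_est_14006, and ran from 0 to 5 without single pools (5 without slow pool 1, 1 without slow pool 4, all other transcripts). For those 5 probes slow pool 1 itself stood high. The count at an unadjusted p under 0.05 was 1721 with probes of a transcript averaged, where fewer features were tested, and ran from 2625 to 3880 without single pools. Slide as a fixed block gave 4043, and the replicate block on pool number gave 0 calls and 3862 at an unadjusted p under 0.05; it changed no call of limma or camera. The female-lineage difference of 0.22 fell to 0.04 after quantile normalization (0.0378, adjusted p = 0.396) and in the authors' table (0.0380, adjusted p = 0.299), kept 0.222 but lost its call with an estimated correlation (adjusted p = 0.174), and ran from 0.19 to 0.26 without single pools. Quantile normalization also brought the median of the 50 brightest other transcripts from 0.15 to -0.02. The male-lineage difference ran from -0.45 to 0.90 without single pools, turning without slow pool 1 or fast pool 4, and passed camera without slow pool 2 (adjusted p = 0.0423) or fast pool 3 (0.0366). Those passes are at the preset correlation of 0.01, while the correlation estimated with all pools was 0.733. The named nuclear genes turned to -0.0876 after quantile normalization, -0.0406 without a filter and -0.118 in the authors' table. The separation of profiles fell to 0.00106 (exact one-sided permutation p = 0.286) without a filter on dim probes. Over all assignments it passed with normexp (0.00494), in the authors' table (0.00467) and without slow pool 4, but with pairs kept it could not pass (smallest exact permutation p 0.125), and it ran from 0.0040 to 0.0076 without single pools. The 19 genes and identifiers followed here, 4 of them serial numbers, gave 453 recomputed values, of which 447 kept direction and side of the threshold. None of the 19 passed under the main settings, so the side kept was always that of not passing. A kept direction also allows a fall in size: COX1_mgal_F went from 0.253 to 0.0128 after quantile normalization. In 4 values the sign turned. These were ND2_mgal_F after quantile normalization (-0.0118) and in the authors' table (-0.0144), CYTB_mgal_F in that table (-0.00327), and 93MgRNAbinding without fast pool 4 (0.0257). The range of 93MgRNAbinding without single pools was -0.129 to 0.0257. Scaling to spike-in probes, chosen after seeing the data, moved the median of all probes from 0.01 to -0.41, so changes are relative to that median. Apart from where stated, the cause was not tested. One value per gene name left the lists as they were, since each name had 1 identifier. Signal over background limits the male-lineage list, of whose 36 probes 9 were well above background on all 8 arrays, and the 2-fold counts, where 670 of 1723 probes were.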

Other observations

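The test of agreement between probes was chosen only after the result was seen. For probes at an unadjusted p under 0.01 between fast and slow pools, 93.4% of 1010 comparisons with other probes of the same transcript had the same sign, where shuffled transcripts gave 50.6%. In 368 transcripts with at least 2 tested probes every probe had an unadjusted p under 0.05 in one direction, 210 higher and 158 lower in fast pools. These counts compare probes on the same arrays and do not bear on differences between pools.

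Probes with identifiers starting mgal_est reached an unadjusted p under 0.05 in 12.3% of cases, those starting mgal_nuc in 7.49% and those starting mcal_est in 5.20%. No test of these shares was run.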
